A study of Homo sapiens with 6 samples.

How the data were processed

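Total RNA from A549 cells infected with control or Nkx2-1 lentivirus was extracted with Trizol and purified further with a cleanup kit, per the labels. From 300 ng of it, biotin-labelled sense-strand cDNA was made and hybridised to Affymetrix arrays, 1 per sample. The deposited values are on a log2 scale, as their range shows, and were made by the authors with RMA, per the submitters' processing notes. RMA stands for background correction, quantile normalization and a summary of the probes of each probe set. The software, its version and its settings are not given in the sources used here. Quantile normalization gives arrays nearly the same distribution, so a change of total RNA per cell would not show. The values carry no detection calls, so dim genes cannot be separated from background and their folds can be understated.

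Arrays were grouped by their titles into 3 Control and 3 Nkx2-1 samples, with replicate numbers from the same titles. All sample columns of the table were used. Probe sets were named from the platform's annotation, whose header gives the year 2016. Of 33297 probe sets, 19460 were paired with 1 gene symbol, 1754 with several and 12083 were not listed there. Symbols were checked through Entrez IDs against a RefSeq gene table of assembly GRCh38.p14, where 19429 matched and 0 changed, and that table was used only for names and neighbours. Genes were tested through their brightest probe set with 1 symbol, by mean log2 level over all arrays. This gave 18417 genes, of which 769 had several such probe sets.

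Differences were Nkx2-1 minus Control. Each gene was tested with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, 2-sided, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Here n is 3 per group throughout. The 32 gene lists were fixed from textbook knowledge and tested with camera at its preset correlation of 0.01, with adjustment over the lists. Set tests with an estimated correlation, fry and camera on ranks were run beside it. For every list, members past the threshold were counted over all genes and adjusted over the list alone. The NKX2-1 probe set also had a 2-sided exact permutation test. Comparisons with random lists matched on mean level were added after the list results were seen, and they and the permutation tests used fixed seeds. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

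The groups, the design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named NKX2-1, the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups did not overlap, leaving out small RNA and uncharacterised symbols. It also named up to 4 called members of each list with the largest change. Other members, and every other gene, are named as chosen after their values were seen. They include LAMP3, LPCAT1, ABCA3, FOXA1, FOXA2, SFTPC, SFTPD, SLC34A2, WNT7B, CDH17, SOX2 among gastric genes, HNF4G, DUSP4, CDKN1A, CEACAM5, ALB, APOA1, NQO1, GCLC and TXNRD1. The alternatives were quantile normalization again, median centring, leaving out the dimmest 25% or 50% of genes, the mean of a gene's probe sets and all probe sets tested. They also included eBayes with trend and robust settings, array weights, the replicate number as a block, leaving out each array, an adjusted p under 0.01, and minimum folds of 1.5 and 2.

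The fit was tested on simulated arrays drawn for all 18417 genes from the real means and spreads, with 50 genes changed at each fold for this comparison. It recovered 44% of 1.25-fold, 80% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes, with 9 false calls among 171. Far fewer genes were changed there than the 39.7% called in the data, and genes were drawn independently. These rates therefore need not hold for the real arrays. On simulated lists with no shift, camera made 0 calls among 32, but genes were drawn independently, so this does not show how camera behaves with correlated genes.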

Results

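Gene expression was measured in A549 cells, an established human lung adenocarcinoma line, after infection with a lentivirus that expresses Nkx2-1 or with a control lentivirus. NKX2-1 is a homeodomain transcription factor of lung and thyroid epithelium. The series holds 3 Control and 3 Nkx2-1 arrays, and its stated purpose was to find the genes that this factor influences. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision. Median log2 levels over all 33297 probe sets lay between 7.43 for Control replicate 2 and 7.50 for Control replicate 3. Over the 18417 genes tested, Pearson correlations across genes were 0.99625 to 0.99846 within groups and 0.95454 to 0.95883 between groups. The first principal component held 92.0% of the variance and the second 3.82%.

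The NKX2-1 probe set itself was close to flat. Its log2 level was 6.85 ± 0.0501 in Control and 6.98 ± 0.0957 in Nkx2-1 (SD, n = 3 each), a difference of 0.127 with a 95% confidence interval of -0.0172 to 0.271. The limma adjusted p was 0.154. The 2-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The control level lay at percentile 29.0 of all genes. Where this probe set lies on the transcript and which cDNA the vector carried are not given in the sources used here, so the probe set does not check the labels of the arrays.

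The Nkx2-1 arrays differed widely from Control. CDH11, a mesenchymal cadherin, was 85.8-fold higher, with a log2 level of 12.57 ± 0.0263 against 6.15 ± 0.0689 (SD, n = 3 each). SFTPB, which encodes surfactant protein B, was 49.5-fold higher, and CD274, which encodes the immune checkpoint ligand PD-L1, was 48.2-fold higher. KIT, a receptor tyrosine kinase, was 41.1-fold higher. NTS, the precursor of neurotensin, was 137.3-fold lower, with a log2 level of 4.43 ± 0.167 against 11.53 ± 0.0817 (SD, n = 3 each). The neural adhesion gene CNTN1 was 110.2-fold lower, the urothelial tetraspanin UPK1B 53.5-fold lower and the prostaglandin synthase PTGS2 47.4-fold lower.

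In all, 7306 of 18417 genes, or 39.7%, changed at a limma adjusted p under 0.05, 3362 higher and 3944 lower in Nkx2-1. Of these, 992 changed at least 2-fold, 447 higher and 545 lower, and 113 changed at least 8-fold. The other genes among the 12 largest increases were NRK, PRUNE2, SLC6A14, EDIL3, TIMP3, CYRIA, CLIC2 and ATP8B4, with log2 differences from 5.62 for NRK to 4.63 for ATP8B4. Besides NTS, CNTN1, UPK1B and PTGS2, the 12 largest decreases were PLA2G4A, MMP7, BICC1, TMEM47, MTUS1, NR5A2, TM4SF4 and DAB2, from -5.13 for PLA2G4A to -4.54 for DAB2 on the log2 scale. The highest limma adjusted p among these 24 genes was 3.22e-09, for PTGS2. At 9310 genes, or 50.6%, all arrays of one group lay above all arrays of the other, where chance gives 10%. Levels near background can understate a fold, and NTS, CNTN1, PLA2G4A, DAB2, CLIC2, SLC6A14 and NRK lay in one group below 5.37, the level that 10% of genes do not reach. That level is not a measured background. In Control, the median level was 6.37 for the leukocyte list and 6.82 for the endothelial list. CDH11, CD274, KIT, UPK1B, PTGS2, CYRIA, MMP7, PRUNE2, NR5A2, EDIL3 and MTUS1 also lay below 6.37 in one group, so their folds can be understated too.

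**Figure D1:**
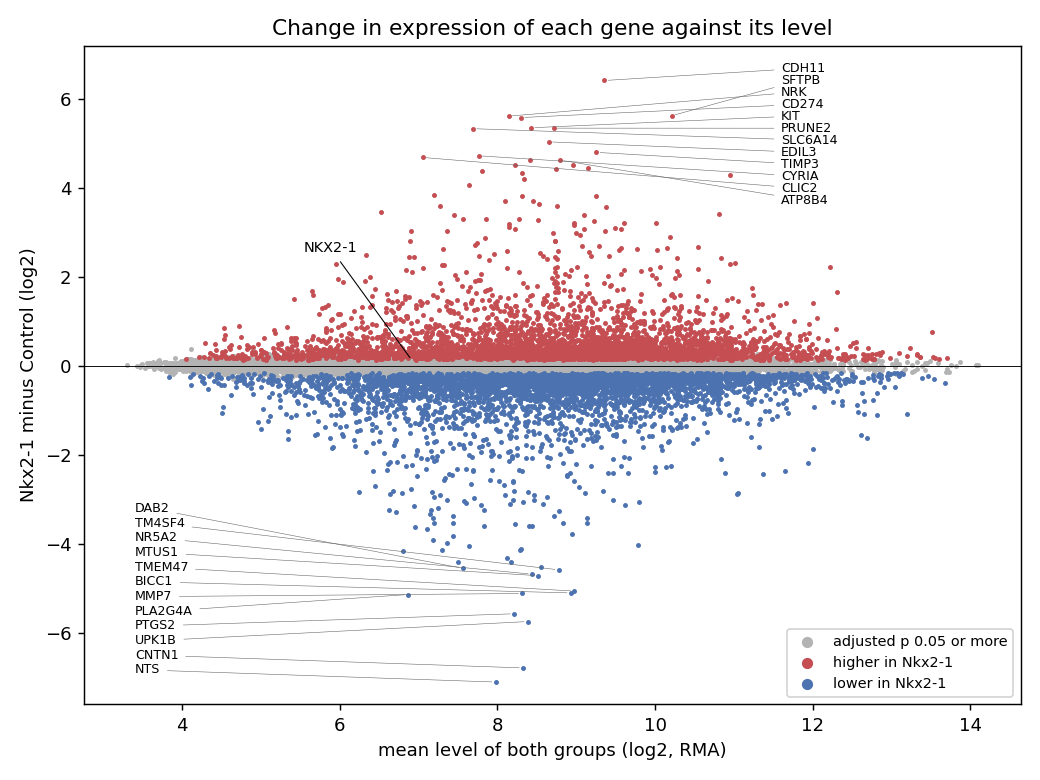
Difference in log2 level, Nkx2-1 minus Control, against the mean log2 level of both groups for each of 18417 genes. Red and blue points passed the limma test as higher (3362) and lower (3944), grey points did not, and the 12 largest changes in each direction are named; NKX2-1 lies near 0.

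Genes of surfactant and alveolar type II cells rose as a group. SFTPB and NAPSA, an aspartic protease that processes surfactant protein B, rose by 5.63 and 4.52 on the log2 scale. DMBT1 rose by 3.19, LAMP3 by 2.47, LPCAT1, which makes surfactant phospholipid, by 1.60 and ABCA3, a lipid transporter, by 1.10. LRRK2, FOXA1 and FOXA2 were lower, at -2.85, -1.33 and -0.77. Of 21 measured members, 10 rose, 3 fell and 8 did not pass the test, with the same counts adjusted over the list alone. SFTPC and SFTPD rose by 0.21 and 0.22, while SLC34A2 differed by 0.15 without passing. The list median was 0.15, with a camera adjusted p of 0.0214, and adjusted p = 0.265 with an estimated correlation. Over all camera alternatives the adjusted p ran from 0.0105 to 0.265, and on ranks it was 0.0814.

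Other lung lists did not pass the camera test as a whole. Of 19 measured genes reported elsewhere as NKX2-1 targets outside the surfactant system, 7 rose and 6 fell, and 8 and 6 when adjusted over the list alone. LMO3, a LIM-only cofactor, rose by 3.60, the carboxypeptidase CPM by 3.58, the phosphatase DUSP6 by 3.10 and MYBPH by 2.15, while WNT7B fell by 1.20 (camera adjusted p = 0.336). Whether any of those reports drew on these arrays was not checked, so this list is not independent evidence. The list also does not record which members were reported as raised or as lowered. Its counts and its test of 1 direction therefore cannot show whether the genes moved as reported. Outside the gene comparison, the probe set shared by HMGA2 and ELAC2 was higher by 0.55 and that of OCLN and OCLNP1 by 0.43. In alveolar type I genes, 6 of 17 rose and 6 fell, with HOPX higher by 1.22 and RTKN2 lower at -1.29 (camera adjusted p = 0.729). Of 16 airway secretory genes, 1 rose and 5 fell. Among these the protease inhibitor SLPI differed by -3.06, ELF3 by -1.57, ALDH1A1 by -1.55 and LCN2 by -1.18 (camera adjusted p = 0.314). In the mucous list, 2 of 23 rose and 6 fell. AGR2, a disulfide isomerase of mucous cells, fell by 3.77 and the gel-forming mucin MUC5B was 10.6-fold lower, and CREB3L1 rose by 1.39 (camera adjusted p = 0.36). Counts adjusted over the list alone were the same for the alveolar type I, airway secretory and mucous lists. Medians of the airway secretory and mucous lists were 0.0054 and 0.013, while their means were -0.40 and -0.37 and the test pointed down. Without the dimmest 50% of genes both passed as lower, with medians of -1.56 and -1.25 and camera adjusted p of 0.00608 and 0.0106. These were the lowest of all camera alternatives, whose highest was 0.778 for each list. That filter left only part of each list, as LCN2 and MUC13 dropped out. It kept genes by their mean over all arrays, with a cut at 8.017. SLPI, AGR2 and MUC5B passed it through Control levels of 9.85, 10.83 and 10.84, and lay at 6.79, 7.06 and 7.43 in Nkx2-1. The filter can thus favour members that fell, so these 2 calls add no support. MUC5AC was not analysed here.

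A subset of plasma protein genes typical of hepatocytes fell strongly, while most of the list did not pass the test. The complement genes C5 and C3 were lower, at -4.13 and -3.52 on the log2 scale. The fibrinogen-like gene FGL1 differed by -4.15 and the fibrinogen chain FGA by -3.82. ALB and APOA1 differed by 0.037 and 0.15 without passing. Of 32 members, 1 rose, 11 fell and 20 did not pass, with the same counts adjusted over the list alone. The median was -0.034, with a camera adjusted p of 0.0209, and adjusted p = 0.265 with an estimated correlation, in a range of 0.00142 to 0.265 over all camera alternatives. Without Control replicate 3 the median was 0.0047 and the adjusted p 0.0695, and on ranks the adjusted p was 0.175.

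Genes of gastric and intestinal epithelium moved in both directions. TM4SF4 and TM4SF20 were lower, at -4.58 and -3.61 on the log2 scale, as were the cadherin CDH17 at -2.87, SOX2 at -1.84 and HNF4G at -1.52. CEACAM6 and VSIG1 rose by 4.30 and 3.31. Of 29 members, 5 rose and 11 fell, also when adjusted over the list alone (camera adjusted p = 0.287). CEACAM5, a related family member, rose by 0.65. HNF4A was not analysed here.

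**Figure D2:**
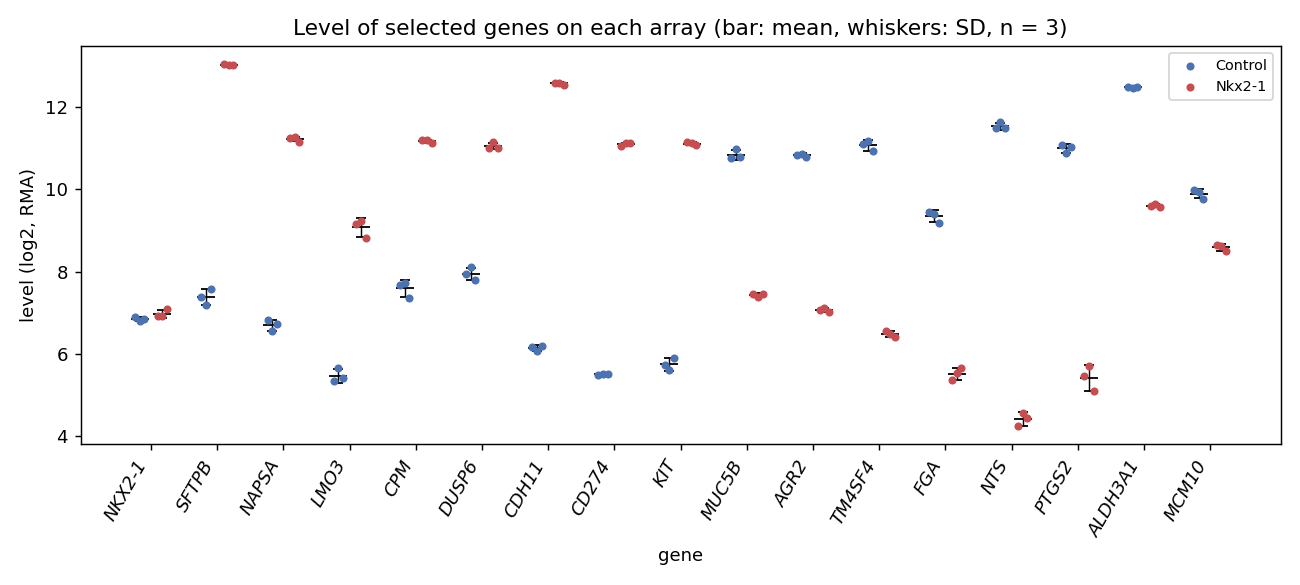
Log2 level of 17 genes on each of the 3 Control (blue) and 3 Nkx2-1 (red) arrays, with the mean as a bar and the SD as whiskers. NKX2-1 differed by 0.127, while SFTPB was higher by 5.63 and NTS differed by -7.10 on the log2 scale.

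Immediate targets and feedback regulators of MAPK signalling rose as a group. DUSP6 rose by 3.10 and HBEGF, an EGF receptor ligand, by 3.03 on the log2 scale. The transcription factors EGR1 and JUN rose by 1.81 and 1.77, and DUSP4 fell by 1.34. Of 22 members, 15 rose and 5 fell, also when adjusted over the list alone. The median was 0.44, with a camera adjusted p of 0.00242, and adjusted p = 0.265 with an estimated correlation, in a range of 0.00118 to 0.265 over all camera alternatives.

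Lists of inflammatory, mesenchymal and junction genes held large changes of opposite sign. In the NF-kB and cytokine list, IL6 rose by 3.32, CXCL2 by 2.70 and the NF-kB inhibitor TNFAIP3 by 2.59, while PTGS2 fell by 5.57. There, 12 of 27 rose and 7 fell, and 14 and 7 when adjusted over the list alone (camera adjusted p = 0.0617). That list passed in 1 of 16 camera alternatives, without Nkx2-1 replicate 2 (adjusted p = 0.0474, in a range of 0.0474 to 0.265). In the mesenchymal list, CDH11 rose by 6.42, the gelatinase MMP2 by 3.22, the matrix protein TNC by 2.52 and INHBA by 2.39. Of its 33 members, 14 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.062). That list passed in 4 of 16 camera alternatives, with adjusted p from 0.00608 to 0.265. Among epithelial junction and keratin genes, EPCAM and DSC2 rose by 1.42 and 1.11, and KRT8 and PKP2 were lower, at -1.61 and -1.20. There, 9 of 29 rose and 11 fell, and 9 and 12 when adjusted over the list alone (camera adjusted p = 0.729, median 0.041, mean -0.052, test down). In the TGF-beta and YAP response, ANKRD1 rose by 1.19 and CCN2 by 0.88, and PMEPA1 and SKIL were lower, at -1.12 and -1.07. Of 22 members, 7 rose and 10 fell, and 9 and 10 when adjusted over the list alone (camera adjusted p = 0.66).

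Cell cycle genes fell broadly and by modest amounts. CCNE2, an S-phase cyclin, differed by -1.90 on the log2 scale, the replication genes GINS1 and MCM10 by -1.36 and -1.31, and the transcription factor E2F8 was 2.37-fold lower. Of 50 members, 40 fell, 1 rose and 9 did not pass, with the same counts adjusted over the list alone. The median was -0.52, with a camera adjusted p of 1.61e-12, and adjusted p = 0.395 with an estimated correlation, in a range of 5.81e-14 to 0.395 over all camera alternatives.

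Targets of p53 rose as a group, led by the death receptor gene FAS at 2.08 and the stress gene SESN2 at 1.69. TP53I3 rose by 0.87, and GDF15 fell by 1.02. CDKN1A, the best known member, differed by -0.013 and did not pass. Of 24 members, 11 rose and 2 fell, and 12 and 3 when adjusted over the list alone. The median was 0.14, with a camera adjusted p of 0.0348, and adjusted p = 0.398 with an estimated correlation, in a range of 0.0215 to 0.398 over all camera alternatives. It was 0.0745 without Control replicate 3, 0.0552 on ranks and 0.0553 without the dimmest 50% of genes.

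Targets of NRF2, the regulator of antioxidant genes, fell. ALDH3A1 differed by -2.88, AKR1C3 by -2.43, AKR1B10 by -2.35 and ALDH1A1 by -1.55 on the log2 scale. NQO1, GCLC and TXNRD1, among the best known targets, differed by -0.062, -0.00017 and -0.14 without passing. Of 27 members, 22 fell, 0 rose and 5 did not pass in limma, and 23 fell when adjusted over the list alone. The median was -0.36, with a camera adjusted p of 2.23e-10, and adjusted p = 0.265 with an estimated correlation, in a range of 1.37e-13 to 0.265 over all camera alternatives. The AKR1C genes are near-identical copies, so the share of each is uncertain.

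Cholesterol synthesis genes also fell, with HMGCS1 lower by a log2 difference of -1.90, INSIG1 at -1.01, SQLE at -0.78 and IDI1 at -0.69. Of 18 members, 10 fell and 1 rose, and 11 and 1 when adjusted over the list alone. The median was -0.23, with a camera adjusted p of 0.000634, and adjusted p = 0.265 with an estimated correlation, in a range of 0.000419 to 0.265 over all camera alternatives. In lipid synthesis and storage, ACSL5 rose by 3.83, LPIN1 by 1.26 and ACSL4 by 0.86, and ACACB fell by 0.82. There, 7 of 25 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.931). That list had a median of -0.044 and a mean of 0.15, and the test pointed down.

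Hypoxia and glycolysis genes rose as a group. The hexokinase HK2 rose by 2.82, the growth factor VEGFA by 1.33 and the kinase PDK1 by 1.17, and ADM fell by 1.42. Of 26 members, 13 rose and 5 fell, and 15 and 5 when adjusted over the list alone. The median was 0.17, with a camera adjusted p of 0.0209, and adjusted p = 0.502 with an estimated correlation. Over all camera alternatives it ran from 0.00417 to 0.502, and it was 0.0695 without Control replicate 3.

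Cytosolic ribosomal protein genes rose slightly, with RPS23, RPL13, RPL3 and RPL30 higher by 0.35, 0.34, 0.29 and 0.28. Of 32 members, 15 rose and 0 fell in limma, and 17 rose when adjusted over the list alone. The median was 0.16, with a camera adjusted p of 0.000539, and adjusted p = 0.265 with an estimated correlation, in a range of 2.14e-06 to 0.265 over all camera alternatives. Ribosomal protein genes have many pseudogene copies, so their signals are uncertain. Nuclear oxidative phosphorylation genes had 4 of 34 higher and 13 lower, also when adjusted over the list alone, with COX7B at -0.72, NDUFA2 at -0.56 and SDHD at 0.35 (camera adjusted p = 0.307). In the unfolded protein response, DDIT3 rose by 2.17, CHAC1 by 1.46, ATF3 by 1.27 and PPP1R15A by 1.22. Of its 26 members, 10 rose and 12 fell, and 11 and 12 when adjusted over the list alone. Its median was -0.016, its mean 0.29 and the test pointed up (camera adjusted p = 0.449).

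The interferon and antigen presentation lists held more decreases than increases and did not pass the camera test. All genes also held more decreases, but less unevenly (3944 against 3362). The NF-kB and cytokine list, given above, held more increases. In the interferon response, SAMD9 was lower at -2.80, HERC6 at -1.07, SAMD9L at -0.84 and HERC5 at -0.62. There, 3 of 37 rose and 12 fell, also when adjusted over the list alone (camera adjusted p = 0.163). Its median was -0.056, below the central 95% of random lists matched on mean level, -0.034 to 0.082. In antigen presentation, HLA-DMB and HLA-DMA, which load class II molecules, were lower, at -3.11 and -1.47, PSMB9 fell by 0.52 and CTSS rose by 1.59. Of its 16 members, 2 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.449). Its median was 0.011, its mean -0.23 and the test pointed down.

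Genes of other tissues in which NKX2-1 acts stayed mostly below the threshold, as did genes in general, of which 39.7% passed. In the thyroid list, 0 of 13 rose and 2 fell in limma, HHEX at -0.89 and DIO2 at -0.71 (camera adjusted p = 0.45). In the ventral forebrain list, 1 of 16 rose and 3 fell, with LHX8 at -2.57, DLX2 at 0.23, SHH at -0.21 and DLX1 at -0.20 (camera adjusted p = 0.729). Its median was 0.016, its mean -0.15 and the test pointed down. Both lists had the same counts adjusted over the list alone. The calls of DLX1, DLX2 and SHH were each lost without at least 1 single array.

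Lists of leukocyte, endothelial, fibroblast, basal, ciliated, neuroendocrine and housekeeping genes did not pass the camera test. Of 23 leukocyte genes, 5 rose and 2 fell, with CD14 at -1.96, CD68 at 0.86, GNLY at 0.41 and ITGAM at -0.27 (camera adjusted p = 0.36). Of 18 endothelial genes, 2 rose and 2 fell, with ESAM at -0.69, KDR at 0.60, CDH5 at -0.24 and PECAM1 at 0.20 (camera adjusted p = 0.788). Of 18 fibroblast genes, MFAP5 and FBLN1 rose by 4.38 and 1.23 and 0 fell in limma (camera adjusted p = 0.36). Of 15 basal and squamous genes, 7 rose and 2 fell, with SOX2 at -1.84, KRT15 at 1.56, DSC3 at -1.19 and IVL at 0.82 (camera adjusted p = 0.287). Of 18 ciliated genes, 0 rose in limma and TPPP3, RFX2, TUBB4B and RSPH1 were lower, at -0.37, -0.32, -0.23 and -0.16 (camera adjusted p = 0.729). Of 15 neuroendocrine genes, 2 rose and 5 fell, with SNAP25 at -1.53, CHGB at -0.84, ENO2 at -0.41 and UCHL1 at -0.41 (camera adjusted p = 0.698). The ciliated and neuroendocrine lists had medians of 0.011 and 0.065, means of -0.026 and -0.15, and tests that pointed down. Of 22 housekeeping genes, 2 rose and 8 fell, with VCP, SNRPD3, CHMP2A and TUBB at -0.37, -0.36, -0.32 and -0.28 (camera adjusted p = 0.307). Adjusted over the list alone, the counts of these 7 lists were the same. PECAM1, CDH5 and RSPH1 each lost the call in at least 1 alternative.

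Of the 32 lists, camera called 9, 5 higher and 4 lower. With an estimated correlation 0 were called, 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.265. The fry test, which asks whether a list moves on balance in one direction without comparing it with other genes, called 25 lists, among them all 9 in the same direction. Against 10000 random lists matched on mean level, 12 medians lay outside the central 95%, those of the 9 called lists and of the mesenchymal, interferon and NF-kB lists.

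**Figure D3:**
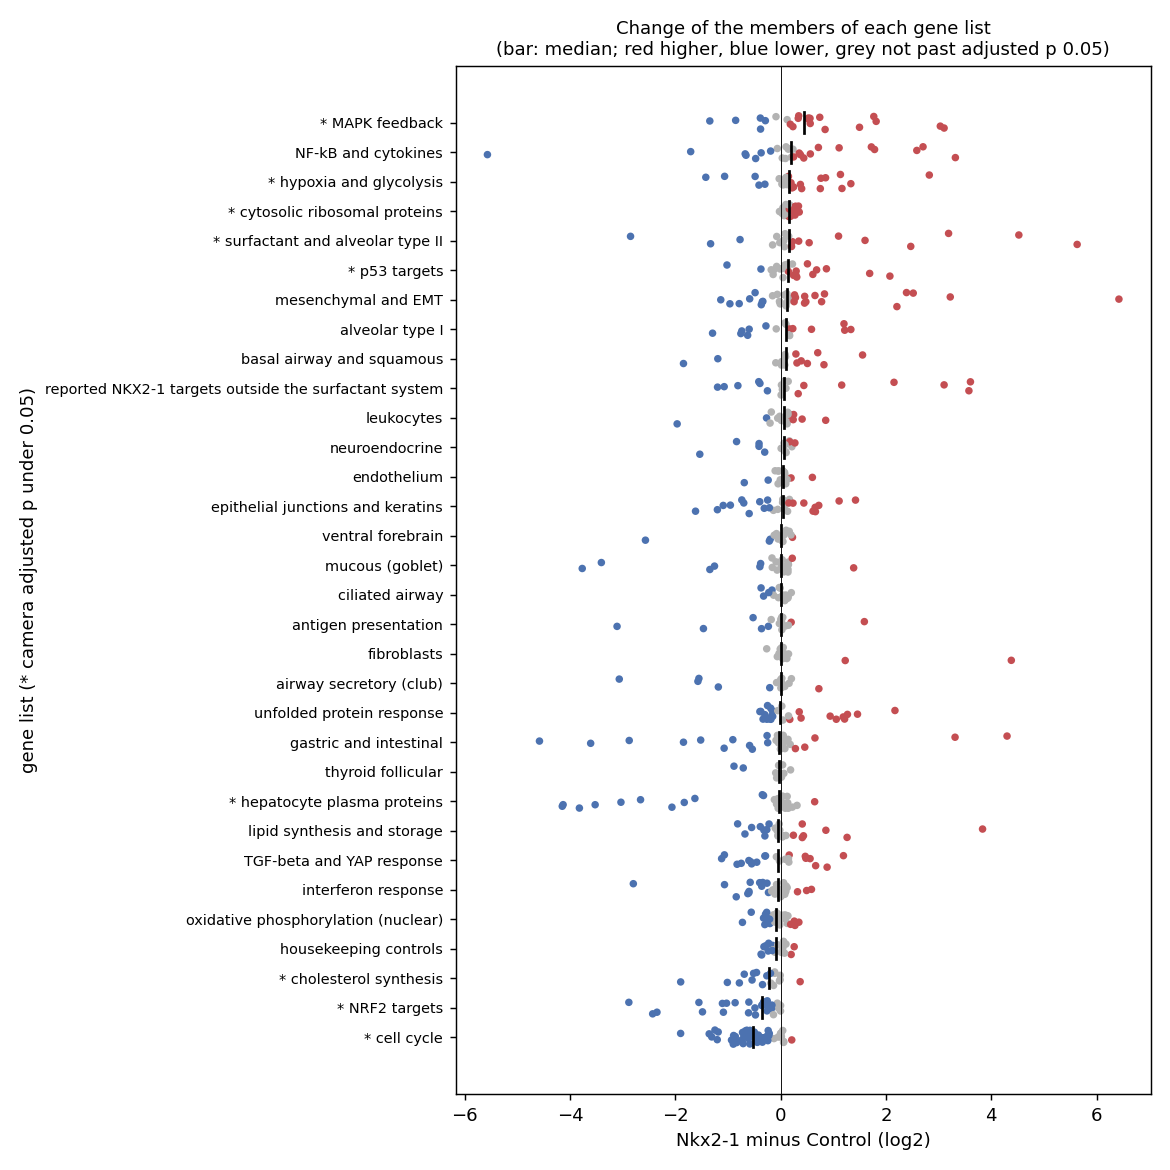
Difference in log2 level, Nkx2-1 minus Control, of each measured member of the 32 gene lists, ordered by list median (black bar). Red and blue points passed the limma test as higher and lower, grey points did not, and an asterisk marks the 9 lists called by camera; cell cycle had the lowest median, at -0.52, and MAPK feedback the highest, at 0.44.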

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

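Of the tests in this part, the splits of probe sets without 1 gene symbol and the copy number test were written before their results were seen. The tests of exchanged labels, of a single wrong label, of the probe set and of the count of genes over other splits were chosen after the result was seen.

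Probe sets outside the gene comparison also differed between the groups. Whether those that the annotation does not list read genes or control sequences is not known here. Of these 12083, 993 were higher in Nkx2-1 and 715 lower by limma. Of the 1754 paired with several symbols, 245 were higher and 238 lower. The largest increases among unlisted probe sets were 4.673 for probe set 7896712 and 4.316 for probe set 7969531 on the log2 scale. The largest decreases were -4.739 for probe set 7908459 and -3.669 for probe set 7967107. Among those with several symbols, the probe set shared by KRT16 and its pseudogenes was higher by 3.389, that of SFTPA2 and SFTPA1 by 2.355 and that of LOC653653 and AP1S2 by 1.301, while that of NPY4R2 and NPY4R differed by -3.657 and that of CNTNAP3 and its copies by -4.068. At least 2-fold changes were more often decreases, with 43 higher and 56 lower among the unlisted and 11 higher and 27 lower among those with several symbols. In the real split 2191 such probe sets passed, and the highest of the other splits gave 0. Those splits mix both groups, so the group difference widens their residual spread and few calls were likely beforehand. Only 10 splits exist, 1 of which gave as many, too few for a share under 0.05.

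A wide change with a flat NKX2-1 probe set is the first pattern weighed. An exchange of the labels is argued against by the surfactant and alveolar type II list, where 10 of 21 members rose and 3 fell, as far as the factor raises these genes. A single wrong label is argued against by correlations of at least 0.99625 within groups and at most 0.95883 between them. Different copy number of large regions was weighed only as the source of changes of at least 2-fold. Only 0.202% of genes so changed lay in the 1 of 379 windows of up to 50 neighbouring genes with a median over 0.3 in size. The last window of a chromosome can hold fewer genes, so its median is less certain. This argues against it for these genes alone. Smaller regional shifts stay open: the SD of window medians was 0.0566, against a mean of 0.0337 and a highest of 0.0682 in 1000 permutations. The Y chromosome was not scanned. Whether the probe set fails to read the transcript of the vector, or that transcript was low, cannot be told apart from a difference of 0.127, since neither probe positions nor the cDNA is known here. The real split called 7306 genes and the highest of the others 0, and 1 of the 10 splits gave as many, too few for a share under 0.05. Each of the others mixes both groups, so the group difference widens its residual spread. Few calls there were thus likely beforehand. An effect of the factor stays open as untested beyond the design.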

How the results depend on the processing

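All alternatives were planned and none was added. Counts of changed genes stayed within 1.5 times 7306 in 10 of 12 settings besides leaving out arrays, and ran from 6279 to 7421 (2782 to 3506 higher, 3438 to 3915 lower) with an array left out. A minimum of 1.5-fold left 2160 genes (964 higher, 1196 lower) and of 2-fold 992 (447 higher, 545 lower), as fewer genes can pass. Array weights gave 8677, every probe set 8904 and the brighter 50% of genes 5666. The 992 genes changed at least 2-fold remained called in the same direction wherever tested under the scalings, array weights, block and left-out arrays. The NKX2-1 difference stayed below the threshold, from 0.069 to 0.144 over the 6 settings run for it and 0.072 to 0.156 with an array left out. Lists called numbered 6 to 10 with an array left out, 25 under fry, 0 with an estimated correlation and 6 on ranks; the cause was not tested. Lipid synthesis and storage, with a median of -0.044, pointed up under fry and down under camera; the cause was not tested. Without Control replicate 3, 6 lists were called, the hepatocyte, p53 and hypoxia lists being lost. Of 1919 values of the 141 named genes, 1900 kept call and direction, 19 lost the call (6 genes, 17 with an array left out) and 0 reversed. These genes, and the 992, were chosen for their calls in the same arrays, so keeping the call was largely set beforehand. Whether replicate numbers pair the arrays stays open. Deviations of same-numbered arrays correlated at -0.017, 0.207 and 0.359, the last the highest of all pairs between groups. Only 3 of 6 arrays correlated best with their own number. Array weights were lowest for Control replicate 3 (0.459) and Nkx2-1 replicate 3 (0.549). With the replicate block 7845 genes (3690 higher, 4155 lower) and 9 lists were called, and NKX2-1 differed by 0.127. Arrays have no detection calls here, so signal over background limits folds of dim genes.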

Other observations

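Tests of the cell cycle and NRF2 lists in this part, and the scan of symbol families, were chosen after the result was seen; the splits of lists and of families were written before theirs. Genes outside the rule were named after their values were seen.

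Metallothionein genes, which encode small metal-binding proteins, were higher together. Of 15 genes whose symbols start with MT and a digit, 14 passed as higher and 0 as lower by limma, with a median of 0.61 on the log2 scale. The 14 include MT1DP, MT1IP, MT1JP and MT1P3, whose symbols are those of pseudogenes. MT1X rose by 1.18, MT1G by 0.81 and MT2A by 0.76, while MT3 differed by 0.065 without passing. They were the strongest of 330 families of symbols tested by camera (adjusted p = 4.87e-06, and adjusted p = 1 with an estimated correlation). MT1 genes are near-identical copies, so the share of each is uncertain. The 7 families called were MT, RPL, RPS and SNORD up and MCM, KIF and AKR down, each with adjusted p = 1 with an estimated correlation. The RPS symbols also cover S6 kinase genes, which are not ribosomal proteins, and these hold its largest rises, RPS6KA2 at 3.29 and RPS6KA5 at 1.30. Of the 10 splits, 7 called as many families, and the highest of the others called 40. What those calls follow was not tested, so family calls are weak. The MT family passed in 4 of the 9 other splits, which each hold both groups in unequal number and so keep part of the real difference. Whether that kept part gave the MT calls was not tested, and some of those splits called more families than the real one.

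PDCD1LG2, which encodes the second ligand of PD-1, rose by 2.17 on the log2 scale beside CD274. NFE2L2, which encodes NRF2, rose by 0.35 and KEAP1, which encodes an inhibitor of NRF2, fell by 0.23, while 22 of 27 measured NRF2 targets fell. The activity of these proteins was not measured. Whether KEAP1 is intact in these cells is not given in the sources used here, so its RNA is no measure of NRF2 inhibition. NKX2-8 and PAX9, neighbours of NKX2-1, differed by 0.0095 and -0.12 without passing limma.

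Lower cell cycle genes are the second pattern weighed. A shift of genes of that brightness is argued against by the list median of -0.52, against -0.104 to 0.0771 for the central 95% of 10000 random lists matched on mean level. The pattern was stronger in DNA replication than in mitosis genes, which describes it and does not explain it. In genes of no fixed list, 38 of 42 replication genes fell (median -0.64) and 24 of 44 mitosis genes (median -0.28), a difference of -0.367 (permutation p = 3e-05), and -0.364 without KIF genes (permutation p = 0.00037), but the permutation treats correlated genes as independent. Proliferation itself was not measured here.

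Lower NRF2 targets are the third pattern weighed. A shift of genes of that brightness is argued against by the list median of -0.356, against -0.132 to 0.115 for random lists matched on mean level. Signal shared among AKR and ALDH copies is argued against as the whole cause, since 16 of the 21 other members fell, with a median of -0.27. NQO1, GCLC and TXNRD1, at -0.062, -0.00017 and -0.14, did not pass limma, so the fall was not shared by all targets, and its cause was not tested. The call had an adjusted p = 0.265 with an estimated correlation.

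Over lists, the real split called 9 and the others 3 to 7, and 1 of the 10 splits gave as many, too few for a share under 0.05. With an estimated correlation 0 of 32 lists were called, with a lowest adjusted p of 0.265. Correlation alone does not account for higher p-values in every list. For the hepatocyte list the estimate, 0.00589, lay below the preset 0.01, yet the unadjusted camera p rose from 0.00456 to 0.0405. In the mesenchymal list the estimate was -0.00729 and that p rose from 0.0213 to 0.0573. The loss of calls thus does not by itself show that a list did not move. List calls still depend on the setting, so they are uncertain. Of the 9 other splits, which keep part of the real difference, NRF2 passed in 9, cell cycle in 8, ribosomal proteins in 6, cholesterol in 4, hypoxia in 3, the hepatocyte and MAPK lists in 1 each, and the surfactant and p53 lists in 0. Whether that kept part gave these calls was not tested.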
